A study of Mus musculus with 4 samples.

How the data were processed

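RNA was sequenced from group 3 innate lymphoid cells (ILC3s) of the mouse small intestine. These are lymphocytes without rearranged antigen receptors that make IL-22 and IL-17. Per the series' design text, the cells were sorted as live, low for CD45, without lineage markers such as CD3 and high for CD90.2, and libraries were read on a BGISEQ-500 instrument. There were 4 libraries, 1 per group. One pair was WT and IL-17D knockout (KO) ILC3s, from mice at steady state. CD93-positive and CD93-negative ILC3s came from WT mice. Per the labels' protocols, a cell suspension was kept for 12 h in culture without stimulation before the CD93 sort. The labels give this protocol for every library, and whether the WT and KO cells were also cultured is not given in the sources used here.

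The values used are FPKM (fragments per kilobase of gene, relative to the reads of the library), which the authors computed and deposited. Per the submitters' processing notes, the tools were Bowtie2, featureCounts of the Subread package, edgeR and DESeq2, and the genome build was mm10; their order, settings and versions, and the gene annotation, are not given in the sources used here. Each library had its own deposited FPKM table, and each pair had a joint one; all 15242 rows of the KO and WT pair and all 12546 rows of the CD93 pair held equal values in both. The 2 pairs were processed with different gene sets: 11072 of 15242 names in the first and 12399 of 12546 in the second were in GENCODE M21, and 3945 names of the first were clone names against 0 of the second. Comparisons were therefore made within a pair, and levels are not set across pairs. Of the names in the KO and WT pair, 18 had the form of calendar dates, as spreadsheet programs make from some gene symbols, and 1 of these names filled 2 rows. They were kept in the counts of genes and not named.

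Numbers of reads were recovered from the deposited FPKM. The FPKM of a gene times its union exon length in GENCODE M21 was a whole multiple of 1 step per library, within 0.02 reads, for 92.1% of the KO, 91.9% of the WT, 98.1% of the CD93-positive and 98.2% of the CD93-negative values above 0 that had a length. The step gives the total behind the scaling to library size: 27002582 for KO, 26087274 for WT, 11712846 for CD93-positive and 11790580 for CD93-negative ILC3s. Recovered reads summed to 20855709, 21611125, 11406363 and 10740639 in the same libraries, in the other order within each pair. Whether the scaling totals are sequenced reads or adjusted library sizes was not tested. Reads were whole in both libraries for 10152 genes of the KO and WT pair and 12159 genes of the CD93 pair. No row with recovered reads had fewer than 10 over the pair, which fits a filter at that sum in the deposited tables; no source used here states one. Folds of named genes are ratios of FPKM with a 95% exact (Clopper-Pearson) interval from the reads. Where 1 library had 0 reads, the fold is a bound against 3 reads in that library. PCR reads without molecular identifiers are not independent molecules, so intervals and bounds cover counting error only, and they compare libraries, not conditions.

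With 1 library per group there is no replicate error, and no p-value is given across genes. Differences are log2((FPKM + 1) / (FPKM + 1)), which understates the difference of genes at low levels. A gene was measured if it had an FPKM of at least 1 in either library of the pair, and a difference of at least 1 in log2 (2-fold) was counted. Before the data were examined, 35 lists of markers of cell types, pathways and gene families, 764 genes in all, were fixed. For each list with at least 5 measured members, the median difference was set against 10000 random lists of the same size, drawn within 20 bins of mean log2(FPKM + 1). A list is called higher or lower where its median lies outside the central 95% of these random lists. This describes these libraries. About 5% of random lists lie outside these limits by construction, and members of a list are not independent. Named genes were fixed by a rule before the data were examined: in each comparison the 12 highest and 12 lowest differences among genes with an FPKM of at least 5 in a library, without predicted genes, numbered RIKEN and accession names, pseudogenes, small RNAs, mitochondrial genes, receptor segments and histone genes, plus Il17d, Cd93 and members of the lists. Some genes that the rule takes are not reported here. The differences between KO and WT and between CD93-negative and CD93-positive ILC3s were correlated across genes.

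Other pseudocounts (0.1 and 5), filters (none, or an FPKM of at least 5), a 3-fold limit and 3 other scalings were tried, with 9 alternatives added after the data had been seen. The scalings were a common sum per library, as in TPM, the same without mitochondrial, ribosomal protein, small RNA and receptor segment genes, and a median ratio of 1. The lists were run with the first and the last of these. Among the added alternatives were a scaling of both libraries to the mean of their sums, also run on lists, the IL-17 list without Cd93, and Cd93 itself under 3 scalings. The procedure was tested on simulated Poisson counts, with the same mean in both libraries except for raised genes. Only genes with recovered reads and their known lengths were used, which favours exact recovery. The simulated counts had no spread beyond counting error, unlike the KO and WT pair. The shares below are therefore not error rates of these data. With 10152 genes of the KO and WT pair and 198 of the measured genes raised 4-fold, reads were recovered exactly in 100% of genes, 94.9% of the raised genes and 0.0801% of the others were counted as 2-fold, and 3.5% of 200 unchanged lists lay outside the limits. With 12159 genes of the CD93 pair, 200 of them raised 4-fold, these shares were 100%, 100%, 0.0105% and 2%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.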

Results

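The transcriptomes of ILC3s from the mouse small intestine were compared in 2 pairs of libraries. The first pair sets ILC3s of mice without IL-17D, a member of the IL-17 cytokine family, beside those of WT mice. The second sets WT ILC3s that carry CD93, a surface glycoprotein reported as a receptor of IL-17D, beside WT ILC3s that do not. There was 1 library in each of the 4 groups, so no difference has a replicate check. The totals behind the FPKM scaling were 27002582 (KO), 26087274 (WT), 11712846 (CD93-positive) and 11790580 (CD93-negative), which need not equal the reads sequenced. Of the 15242 genes tabulated for the first pair, 12376 were measured, and of the 12546 for the second, 10117. Differences are given as log2 of FPKM + 1, and intervals in parentheses are 95% counting intervals of the FPKM ratio.

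The targeted gene, Il17d, was not analysed here, so the genotype labels were not checked against its expression. Cd93 (ENSMUSG00000027435.8; mm10 chromosome 2, 148436640 to 148443563, minus strand) had an FPKM of 155.0 in CD93-positive and 79.9 in CD93-negative ILC3s, a ratio of 1.94 (1.88 to 2.00). Its direction went with the sort labels, but its log2 difference of 0.948 lay below the 2-fold limit. Actb differed by 0.983 between the same libraries, so Cd93 is a weak check of the sort. In the first pair, Cd93 had an FPKM of 20.5 in the KO and 43.5 in the WT library, 2.12-fold lower in the KO library (2.04 to 2.20).

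The first comparison asks what the loss of IL-17D does to intestinal ILC3s at steady state. Of 23 measured genes of the ILC3 core list, 0 differed by 2-fold, with an FPKM of Il7r, the IL-7 receptor gene, of 303 in KO and 230 in WT and of Il23r, the IL-23 receptor gene, of 243 and 258. The genes farthest above the WT library encode digestive enzymes of the exocrine pancreas. The 15 effector cytokine genes went both ways, with 13 of them under 2-fold and a median of -0.04. The sign of this median turned under the scalings run on lists (0.02 to 0.11), which raised the median of all genes too, and with an FPKM of at least 5 (0.059). Il22, the most abundant of them (ENSMUSG00000074695.3; chromosome 10, 118204942 to 118210047, plus strand), had an FPKM of 11771 in KO and 16102 in WT, 1.37-fold lower (1.36 to 1.37). Il17f was 1.71-fold lower (1.67 to 1.76; 175 and 300), Tnfsf11, which encodes RANKL, was 1.54-fold lower (1.49 to 1.59; 104 and 161), and Il17a was 1.88-fold lower. Csf2, which encodes GM-CSF, was higher, with 1146 in KO and 973 in WT, as was Tnf (46.2 and 32.0). The folds of single genes are on the deposited scale. The summed FPKM was 510427 in KO and 575053 in WT, and Actb, the highest gene of both, had 21853 and 31207. A common sum would raise the KO values relative to WT and so lessen the folds of the lower genes.

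In all, 2058 genes were at least 2-fold higher and 1569 at least 2-fold lower in the KO library, and the median difference of the 12376 measured genes was 0.01. With the pseudocount of 5 these counts were 499 and 322. Scaling both libraries to a common sum moved the median difference of all genes to 0.17 and gave 2962 higher and 1878 lower genes. Genes with few reads made up much of these counts: 40.8% of the 3668 measured genes with 100 to 1000 recovered reads over the pair were at least 2-fold apart, against 4.39% of the 592 genes with at least 10000. In the CD93 pair these shares were 4.55% and 4.82%. Among 9254 genes with at least 50 reads over the KO and WT pair, 910 had 0 reads in 1 of the libraries, 452 of them in KO and 458 in WT.

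**Figure D1:**
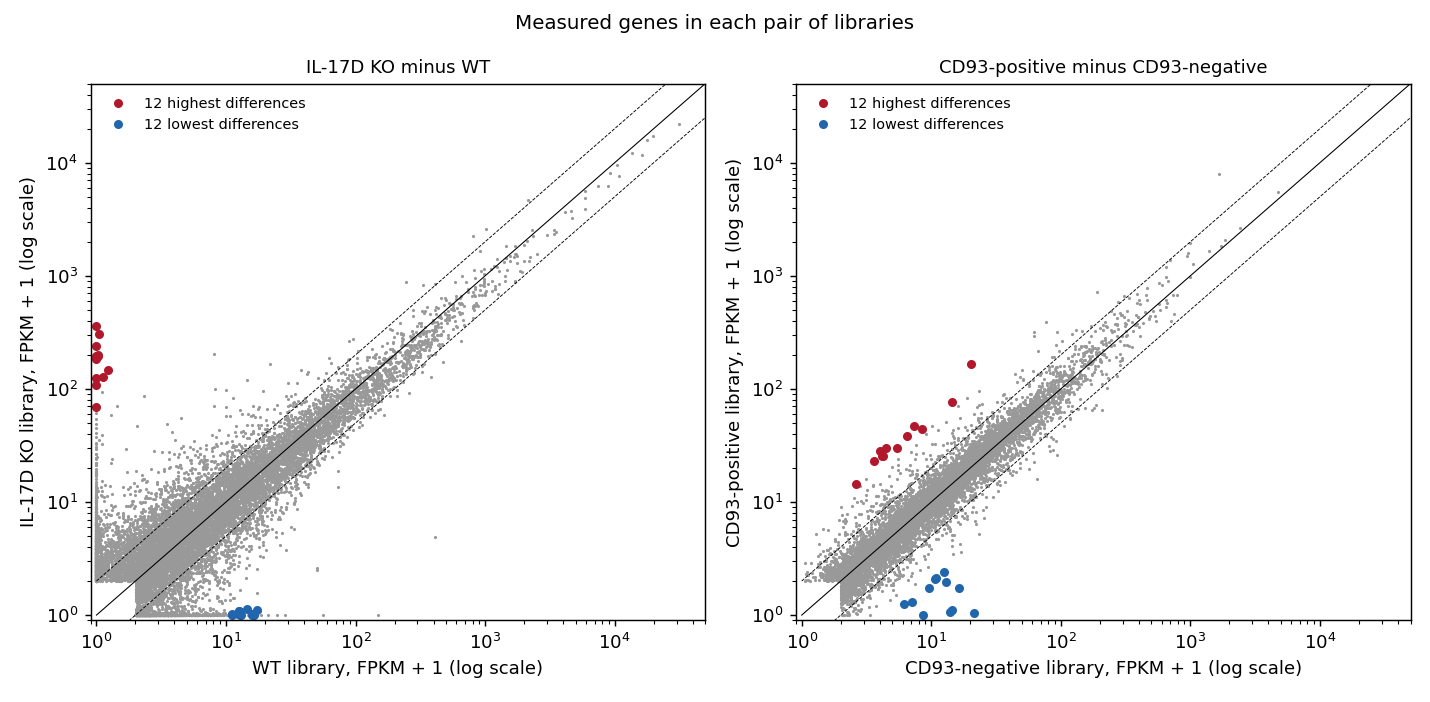
Each point is a measured gene, with its FPKM + 1 in the WT (left) or CD93-negative library (right) on the horizontal log axis and in the KO or CD93-positive library on the vertical log axis; solid lines mark equal values and dashed lines 2-fold differences. Red and blue points are the 12 highest and 12 lowest differences among the genes that could be named; the spread is wider in the KO and WT pair, with 2058 higher and 1569 lower genes against 252 and 196.

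**Figure D2:**
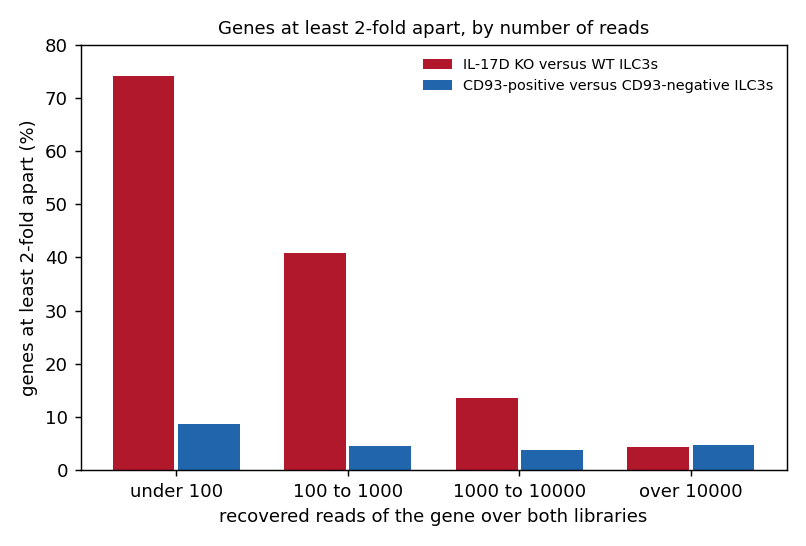
Bars give the percentage of measured genes at least 2-fold apart, by the number of recovered reads of the gene over both libraries, for the KO and WT pair (red) and the CD93 pair (blue). The share falls from 74.1% to 4.39% with the number of reads in the KO and WT pair and lies between 3.74% and 8.61% in the CD93 pair.

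Of the 12 genes with the highest differences in the KO library, 11 encode secreted enzymes of the exocrine pancreas. Amy2a1, a pancreatic amylase gene (ENSMUSG00000070360.5; chromosome 3, 113529403 to 113532428, minus strand), had an FPKM of 359 in KO and 0 in WT, at least 2781-fold higher. The elastase gene Cela2a (240 and 0) was at least 3591-fold, the chymotrypsin-like gene Ctrl (106 and 0) at least 1069-fold and the carboxypeptidase gene Cpb1 (68.2 and 0) at least 1949-fold higher. Rnase1 had 8103 reads in KO and 1 in WT, and the trypsinogen gene Prss2 had 3182 and 5. The lipase gene Pnlip had an FPKM of 123 in KO and was listed at 0 in WT. Amy2a2, Amy2a3, Amy2a4 and Amy2a5, with 183 to 198 in KO, are near-identical copies that share reads with each other, so the value of each copy is uncertain. Lgals3, which encodes galectin-3, completed the 12, with 127 and 0.124. Among the 12 lowest were Lst1, a gene of myeloid cells and lymphocytes (0 and 160 reads; at least 55.2-fold lower), Ndufaf1, an assembly factor of respiratory complex I (0 and 464; at least 160-fold lower), the glycyl-tRNA synthetase gene Gars (11 and 1101; 104-fold lower, 57.7 to 208), Prr5, a component of mTOR complex 2 (5 and 579; 120-fold lower, 51.1 to 371), Cnih1 (1 and 635; 657-fold lower, 118 to 26001) and Rab32 (2 and 618; 320-fold lower, 88.2 to 2647). Tmem138 had an FPKM of 0.0233 in KO and 11.5 in WT, and Fam58b 0.0908 and 11.5. The remaining 4 of the 12 had clone names that are not in the annotation used.

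The epithelial, T cell and B cell lists were higher in the KO library, and that of fibroblasts and smooth muscle was lower. Cells with lineage markers such as CD3 were left out of the sort. Whether these differences lie in the ILC3s or in other cells or their RNA in the samples was not tested. With 1 library per genotype they cannot be read as an effect of IL-17D on ILC3s. Of 14 measured intestinal epithelial genes, 11 were at least 2-fold higher and 1 lower, with a median difference of 1.94, above all 10000 random lists. They included the defensin gene Defa24 (FPKM 887 and 243), the Paneth cell lysozyme gene Lyz1 (141 and 42.2) and the goblet cell gene Tff3 (19.7 and 3.11), while Reg4 was lower (0 and 3.57). Of 18 T cell genes, 10 were at least 2-fold higher and 0 lower (median 1.03, percentile 99.99), among them Cd28 (14.1 and 2.44), Cd3d (40.1 and 18.9) and Trac (177 and 86.7). Of 12 B and plasma cell genes, 5 were higher and 0 lower (median 0.82, percentile 99.98), with Iglc1 at 2579 and 1019 and Ighm at 58.6 and 13.8. Of 15 genes of macrophages, monocytes and dendritic cells, 7 were higher, such as Lyz2 (46.4 and 10.9) and Cd68 (9.10 and 0.884), and 2 lower, Cd209a and Xcr1; the list lay within the random lists. Of 5 genes of fibroblasts and smooth muscle, 3 were lower (median -1.45, percentile 1.02), Lum (0 and 1.86), Gsn (0.106 and 2.02) and Mgp (0.0312 and 2.49), while Vim had 13.6 and 11.7. The endothelial list, with 1 of 5 genes higher and 1 lower, lay within the random lists.

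Among lymphoid lists, the 15 LTi-like genes, which mark lymphoid tissue inducer cells, had 2 members at least 2-fold higher, Lta (FPKM 20.9 and 5.74) and Ccl22 (2.55 and 0), and 0 lower. The list of NCR-positive ILC3s and of ILC1s or NK cells had 5 of 27 higher and 1 lower, with Gzma 3.26-fold (3.03 to 3.52; 113 and 34.6) and Fasl 3.83-fold higher (3.62 to 4.06; 111 and 28.9) and Gzmc lower (50.4 and 107). Of 14 ILC2 genes, 5 were higher, including Gata3 (118 and 55.6), Ccr8 (32.5 and 8.16) and Rnf128 (11.7 and 2.36), and 1 was lower, Areg, which encodes amphiregulin (11.9 and 33.7). These 3 lists and the list of 15 effector cytokines, with Lta higher and Il10 lower (0 and 1.78), lay within the random lists. The ILC2 list (median 0.34) lay above them with an FPKM of at least 5 (0.65, percentile 99.76) and with the common sum (0.64, percentile 97.68). The 6 genes of the IL-17 family and its receptors had a median of -0.77 (percentile 0.91), with 1 at least 2-fold lower, Cd93, and 1 higher, Il17rb (11.5 and 2.15); Il17ra had 1.83 and 3.86.

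Ribosomal protein genes had lower values in the KO library, with a median of -0.51 over 73 genes, below all 10000 random lists. Of these genes 9 were at least 2-fold lower and 3 higher. Clone names took 34.4% of the summed FPKM in the KO and 36.8% in the WT library. Whether reads of ribosomal protein genes were assigned to them was not tested. The 49 genes of oxidative phosphorylation had a median of -0.31 (percentile 1.46), with 2 at least 2-fold lower, Cox6c and Cox7c; with a pseudocount of 5 it lay within the random lists (percentile 3.25). The 13 mitochondrial genes had a median of -0.42, within the random lists. Both these medians and that of the ribosomal proteins stayed negative with a common sum and with a median ratio of 1. The 18 genes of the STAT3 pathway and of the response to IL-23 or IL-1 had a median of 0.33 (percentile 98.18), with Il21r, Pim2 and Prdm1 higher and Il1r2 lower (86.0 and 184); among members with an FPKM of at least 5 the median was -0.058, the other direction, and the list lay within the random lists with a pseudocount of 5 or a common sum. Of 29 genes of immediate early response and dissociation stress, 3 were at least 2-fold lower, the heat shock genes Dnajb1 (170 and 470), Hspa1a (24.5 and 57.2) and Hspa1b (8.52 and 32.7). Of 30 interferon-stimulated genes, 3 were higher and 7 lower, such as Isg15 (12.7 and 33.6). These 2 lists lay within the random lists, as did those of the p38 and JNK (2 of 21 higher, 4 lower) and PI3K, AKT and mTOR pathways (3 of 24 higher, 2 lower), of glycolysis and HIF1A targets (1 of 23 higher, 2 lower), of cholesterol and fatty acid synthesis (2 of 15 higher, 3 lower, among these Idi1 and Insig1), of cell cycle genes (2 of 22 higher, 4 lower), of MHC class I (0 of 12) and class II (3 of 9 higher, 1 lower), of NF-kB (0 of 21 higher, 2 lower), of AHR targets (1 of 6 higher, 1 lower), of chemokine and homing receptors (4 of 20 higher, 1 lower), of apoptosis (4 of 19 higher, 1 lower) and of oxidative and ER stress (2 of 16 higher, 1 lower). The cholesterol and fatty acid list had a median of -0.21. It was 0.28 with the common sum, and -0.53 and below the random lists with an FPKM of at least 5.

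**Figure D3:**
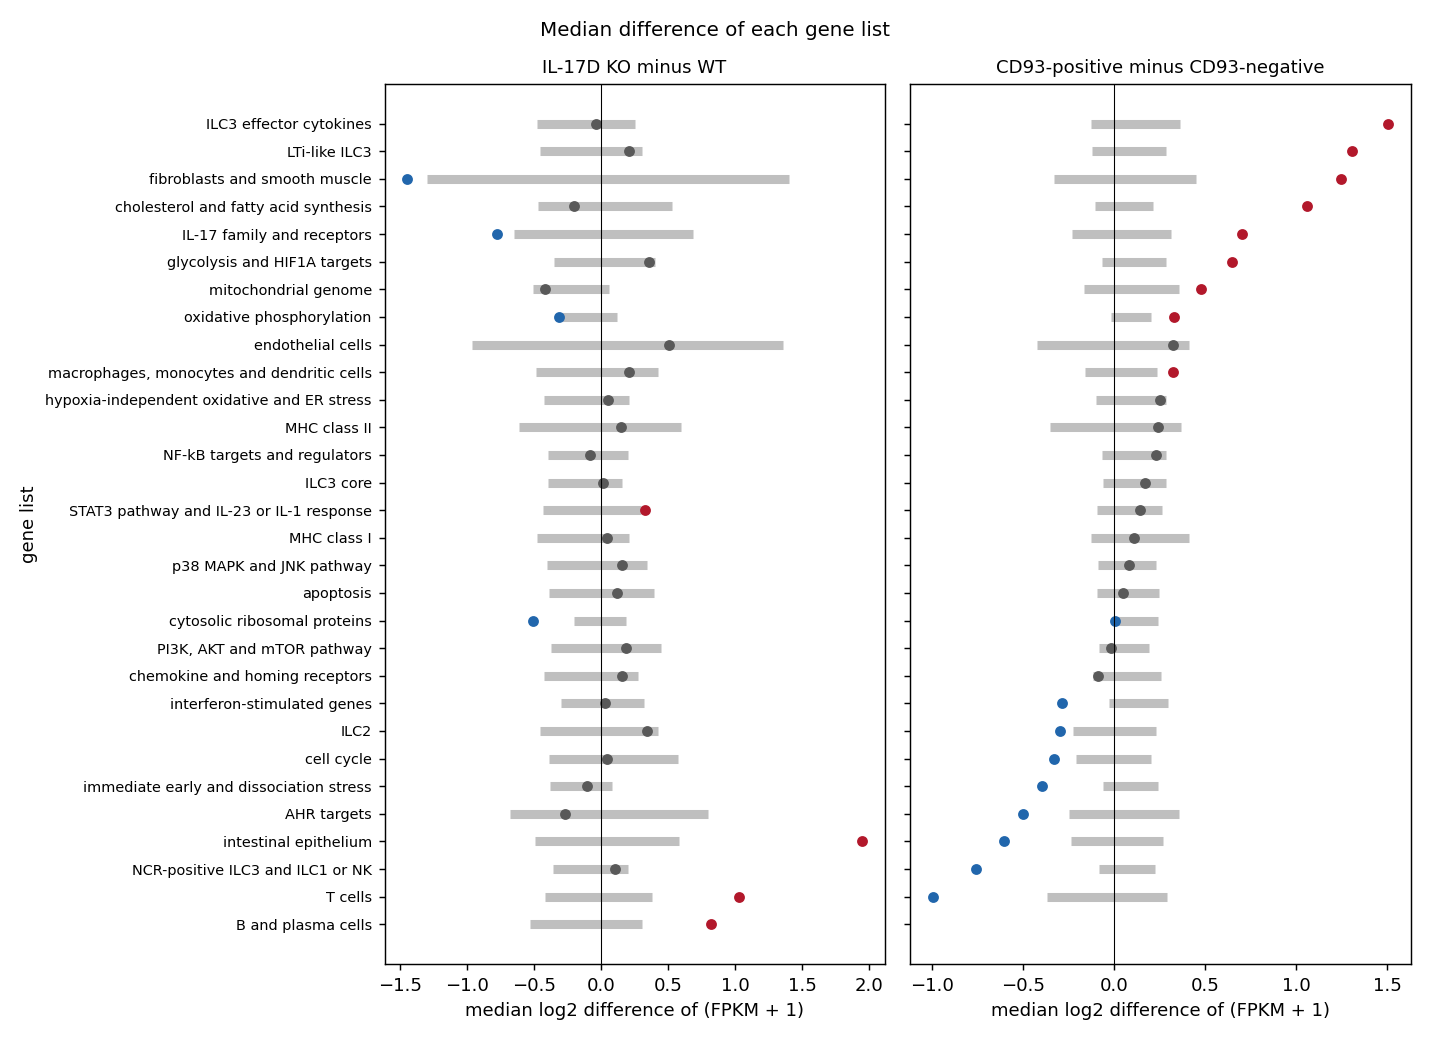
Points give the median log2 difference of the measured members of each gene list, KO minus WT (left) and CD93-positive minus CD93-negative (right), and grey bars the range of the central 95% of 10000 random lists of the same size and expression. Red and blue points lie above and below that range; the LTi-like list stands at 1.30 in the CD93 pair and at 0.21, within the range, in the KO and WT pair.

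The second comparison asks how CD93-positive and CD93-negative ILC3s of WT mice differ. CD93-positive ILC3s had higher expression of effector cytokine genes, of genes of LTi-like ILC3s and of genes of cholesterol synthesis, and lower expression of genes shared with ILC1s and NK cells. Il22 was 4.79-fold higher (4.72 to 4.86), with an FPKM of 7934 in CD93-positive and 1655 in CD93-negative ILC3s. The LTi-like genes Cd4 (ENSMUSG00000023274.14; chromosome 6, 124864692 to 124888221, minus strand) and Ccr6 (ENSMUSG00000040899.14; chromosome 17, 8236043 to 8257141, plus strand) were 9.07-fold (7.62 to 10.9; FPKM 27.3 and 3.01) and 8.30-fold higher (6.70 to 10.4; 28.8 and 3.47). Klrb1c, which encodes NK1.1, was 21.3-fold lower (14.2 to 33.1; 0.721 and 15.3).

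Of the 10117 measured genes, 252 were at least 2-fold higher and 196 at least 2-fold lower in CD93-positive ILC3s, and the median difference was 0.04. The split moved with the scaling and the pseudocount. With both libraries scaled to the mean of their sums, the weight of the pseudocount stays nearly as it was; this alternative was added after the data had been seen. The median difference was then -0.12, with 173 higher and 296 lower genes (36.9% higher). With a common sum as in TPM, which also lessens that weight and takes in 11831 genes, the median difference of all genes was -0.15, with 290 higher and 732 lower genes. Then 28.4% of the counted genes were higher, against 56.2% as deposited. With the same scaling and without mitochondrial, ribosomal protein, small RNA and receptor segment genes, 27.9% were higher.

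Of 13 measured effector cytokine genes, 12 were at least 2-fold higher (median 1.502, above all 10000 random lists). Besides Il22 these included Il17f (7.19-fold, 6.06 to 8.58; FPKM 45.5 and 6.33), Tnfsf11 (291 and 61.5), Lif (81.7 and 17.7), Vegfa (3.84-fold, 3.75 to 3.92; 719 and 188), Tnf (59.1 and 20.2) and Csf2 (214 and 95.9). Ltb, the lymphotoxin beta gene, had the opposite direction with less than 2-fold (75.4 and 114). Of 15 LTi-like genes, 9 were at least 2-fold higher and 1 lower (median 1.30, above all random lists). Tnfsf4 (31.0 and 14.3), Batf3 (6.84 and 1.22), Cxcr5 (11.7 and 3.16) and Nrp1, the neuropilin-1 gene (8.18 and 2.52), were among the higher ones, Ccl22 was lower (7.16 and 19.6), and Ccr7 had 19.2 and 27.0. Tnfsf11, Lta and Ltb are on both lists. Of 24 ILC3 core genes, 3 were at least 2-fold higher, among them Tox2 (26.7 and 5.99) and Bcl2 (23.1 and 6.52), and 0 lower; the list lay within the random lists. The IL-17 family and receptor list, which holds Cd93, the gene of the sort, had a median of 0.70, above all random lists (0.45 without Cd93, percentile 99.58), with Il17f, Il17a (8.53 and 3.62) and Il17re (10.3 and 2.88) higher and Il17rb lower (1.11 and 3.23).

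Of 27 genes of NCR-positive ILC3s and of ILC1s or NK cells, 9 were at least 2-fold lower and 0 higher (median -0.76, below all random lists). The transcription factor gene Tbx21, which encodes T-bet (7.96 and 25.4), the receptor genes Cxcr3 (21.8 and 60.9), Il18r1 (66.5 and 179), Il12rb2 (0.720 and 8.58) and Klrd1 (1.40 and 11.6), and the cytotoxic genes Gzma (27.0 and 82.2), Nkg7 (2.62 and 16.0) and Fasl (3.26 and 15.7) were among them. Ncr1, which encodes NKp46, had 14.8 and 25.7. Il2rb had the opposite direction (977 and 643). Of 8 T cell genes, 4 were lower and 0 higher (median -0.995, below all random lists), such as Cd3g (1.12 and 4.67) and Cd3d (0.141 and 1.87). Of 14 ILC2 genes, Csf2 and Lgmn were higher and Il17rb was lower (median -0.30, percentile 0.62); with an FPKM of at least 5 the list lay within the random lists (percentile 3.97). Of 9 intestinal epithelial genes, 1 was lower, Epcam (1.21 and 4.91), and 0 higher (median -0.61, below all random lists).

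**Figure D4:**
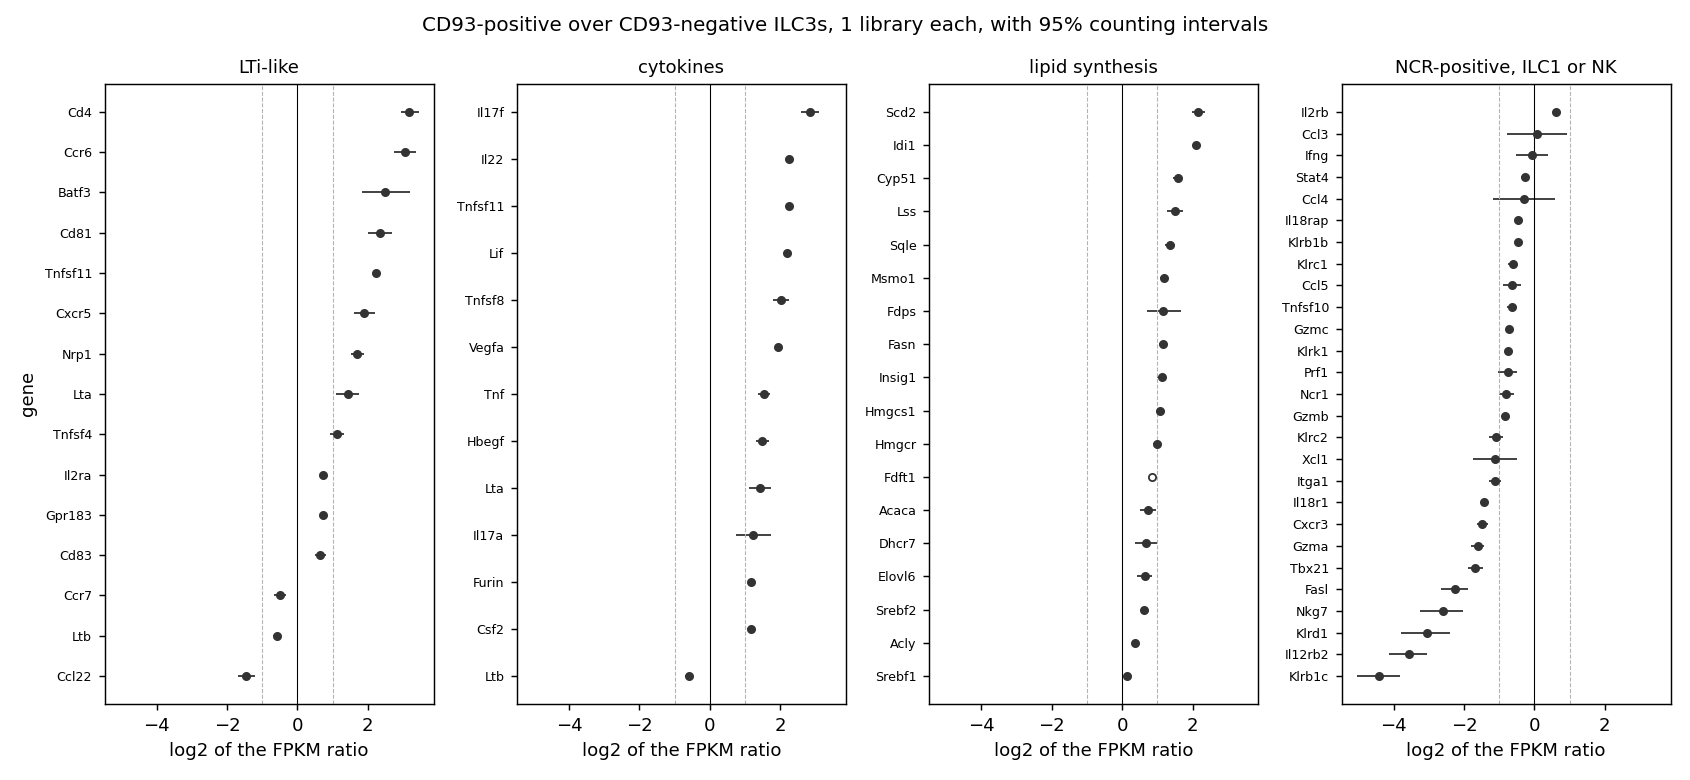
Points give the log2 of the FPKM ratio of CD93-positive over CD93-negative ILC3s for measured members of 4 lists, with some members not shown, bars the 95% counting interval, and dashed lines 2-fold differences; the open point has no recovered reads. Effector cytokine, LTi-like and lipid synthesis genes lie mostly right of 0 and genes of NCR-positive ILC3s, ILC1s or NK cells mostly left, from Cd4 at a ratio of 9.07 to Klrb1c at 0.047.

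Metabolic genes differed as groups. Of 20 genes of cholesterol and fatty acid synthesis, 11 were at least 2-fold higher in CD93-positive ILC3s and 0 lower (median 1.06, above all random lists). Idi1 (95.6 and 22.2), Scd2 (20.4 and 4.55), Sqle (22.9 and 8.92) and Cyp51 (40.1 and 13.4) were among them, and Srebf2, a transcription factor of this pathway, had 89.7 and 57.8. The 23 genes of glycolysis and HIF1A targets had a median of 0.64, above all random lists, with 2 at least 2-fold higher, Hk2 (44.5 and 21.6) and Pgam1 (133 and 65.7). The 48 genes of oxidative phosphorylation had a median of 0.33, above all random lists, and the 12 mitochondrial genes one of 0.47 (percentile 99.76), with 0 and 1 of them at least 2-fold higher. These medians stayed positive with a common sum and with a median ratio of 1. The 77 ribosomal protein genes had a median of 0.01, near 0 but low among random lists (percentile 1.51). With a common sum (-0.17, or -0.16 at the mean of both sums) and with a median ratio of 1 (-0.054) its sign turned, as did that of the median of all genes, and the list stayed below the random lists.

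Of 29 genes of immediate early response and dissociation stress, 7 were at least 2-fold lower in CD93-positive ILC3s (median -0.40, below all random lists), with Nr4a3 (10.1 and 28.7), Klf2 (0.832 and 3.86) and Hspa1b (34.7 and 85.4) among them. Of 33 interferon-stimulated genes, 3 were lower, Ifit2 (17.5 and 43.9), Ifit3 (129 and 272) and Oas2 (5.83 and 20.8), and 0 higher (median -0.29, below all random lists). The lists of AHR targets (0 of 7 by 2-fold; median -0.50, percentile 0.18) and of the cell cycle (1 of 17 lower; median -0.33, percentile 0.19) were low. In the list of fibroblasts and smooth muscle, 4 of 5 genes were higher (median 1.25, percentile 99.99), Vim (120 and 50.2), Gsn (19.1 and 8.89), Lum (11.3 and 3.95) and Pdgfrb (10.8 and 3.65). Of 18 genes of macrophages, monocytes and dendritic cells, 1 was higher, Fcgr1 (2.57 and 0.655), with a median of 0.32 (percentile 99.77), which lay within the random lists among members with an FPKM of at least 5 (percentile 86.14). Of 5 endothelial genes, Cldn5 (23.2 and 4.55) and Eng (11.6 and 3.65) were higher while Pecam1 had 74.4 and 59.4. The p38 and JNK list, with 0 of 22 genes 2-fold apart, and the PI3K, AKT and mTOR list, with 1 of 28, Ddit4 (135 and 43.0), lay within the random lists. The same held for the lists of MHC class I (0 of 13) and class II (0 of 5), NF-kB (2 of 22 higher, Tnf and Tnfrsf9), the STAT3 pathway (2 of 21 higher, Il12rb1 and Il1r2), chemokine and homing receptors (2 of 21 higher, 2 lower), apoptosis (1 of 21 higher, 2 lower) and oxidative and ER stress (1 of 20 higher), and for the endothelial list.

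Outside these lists, the 12 highest differences held Tgm2, which encodes transglutaminase 2 (8.59-fold, 8.05 to 9.17; FPKM 165 and 19.2), the amino acid transporter gene Slc6a7 (22.2 and 2.59), the kinase gene Blk (24.6 and 3.18), Jcad, a gene of endothelial cell junctions (37.4 and 5.45), Tuba8 (24.3 and 3.26), Igfbp4 (13.5 and 1.61), the actin-binding palladin gene Palld (29.0 and 4.46), the urokinase receptor gene Plaur (75.3 and 13.5) and the transcription factor gene Foxs1 (42.9 and 7.50). Among the 12 lowest were Dntt, which encodes terminal deoxynucleotidyl transferase (1 and 555 reads; 551-fold lower, 98.5 to 21815), Ly6d, a marker of lymphoid progenitors (1 and 119 reads; 118-fold lower, 20.8 to 4708), Myl10 (1 and 183 reads; 182-fold lower, 32.2 to 7219), Endou (0 and 246 reads; at least 81.5-fold lower), Foxc2 (12.2-fold lower, 8.48 to 18.3; FPKM 0.971 and 11.9), Cpne7 (0.308 and 6.04), the NK receptor gene Klri1 (1.12 and 9.92), Scin (1.08 and 9.62) and the dipeptidyl peptidase gene Dpp4 (0.257 and 5.14).

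The differences of KO minus WT and of CD93-negative minus CD93-positive ILC3s had a correlation near 0 across the 7595 genes measured in both pairs. Pearson's r was 0.063 and Spearman's rho 0.0424. Genes are not independent replicates, and no p-value is given. The wide spread of genes with few reads in the KO and WT pair can itself lower a correlation. A value near 0 therefore does not show that the loss of IL-17D and the absence of CD93 share no genes. Il22, Il17f, Il17a, Tnfsf11 and Cd93 had lower values both in the KO library and in CD93-negative ILC3s. Csf2, Tnf and Lta were lower in CD93-negative ILC3s and higher in the KO library. These genes were picked after their values were seen.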

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

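With 1 library per group no replicate could be left out. No paired analysis was possible because each group held 1 library. Depth limits the genes with few reads, and the error between libraries was not measured. In the KO and WT pair, the counts of genes at least 2-fold higher and lower (2058 and 1569) were 499 and 322 with a pseudocount of 5, 908 and 611 among genes with an FPKM of at least 5, and 920 and 636 at 3-fold. With alternatives chosen after the data had been seen they were 1160 and 846 among genes with at least 100 recovered reads, 1360 and 1001 among genes whose counting interval excluded a ratio of 1, and 1265 and 961 among protein-coding genes of the annotation. In the CD93 pair, the counts (252 and 196) were 391 and 392 with a pseudocount of 0.1, 109 and 60 with a pseudocount of 5, and 73 and 37 at 3-fold. The lower count alone moved by more than 1.5 times among genes with an FPKM of at least 5 (127), with both libraries scaled to a common sum (732), and with that scaling after mitochondrial, ribosomal protein, small RNA and receptor segment genes were left out (758); with a common sum at the mean of both sums, chosen after the data had been seen, it was 296. Stricter limits and fewer genes lower a count by construction; for the pseudocount of 0.1 and the scalings the cause was not tested. Leaving out the pancreatic genes, also chosen afterwards, moved no count by more than 1.5 times.

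Between 6 and 8 lists of the KO and WT pair (8 as reported) and 13 to 20 of the CD93 pair (18) lay outside the random lists, and the correlation was 0.0492 to 0.0754 with the other pseudocounts and an FPKM of at least 5. Cd93 differed by 0.95 between the sorts, and by 0.91 to 0.96 with the other pseudocounts. With scalings chosen for it after the data had been seen, it differed by 0.78 with the common sum, 0.77 at the mean of both sums and 0.89 with a median ratio of 1, beyond its counting interval and with the same direction. Among lists outside the random lists, the STAT3 list turned from 0.33 to -0.058 in the KO and WT pair among genes with an FPKM of at least 5, and the ribosomal protein list of the CD93 pair from 0.01 to -0.17 with the common sum, to -0.16 at the mean of both sums and to -0.054 with a median ratio of 1. For the STAT3 list the cause was not tested. The scalings moved the median of all genes of the CD93 pair from 0.04 to -0.15, -0.12 and -0.018, so a list so near 0 turns by construction, and the ribosomal protein list stayed below the random lists under each. Of 176 values of single lists under alternatives in the KO and WT pair and 169 in the CD93 pair, 158 and 149 kept their sign and their side of the limits. Another 10 and 13, of lists within the random lists, stayed there with the other sign, such as cholesterol and fatty acid synthesis in the KO and WT pair (0.28 with the common sum) and the endothelial list in the CD93 pair (-0.51). A further 4 and 2 came to lie within the random lists and 3 and 2 outside them. No gene among the 12 highest and 12 lowest changed direction. No alternative was run for Il17d, which was not analysed here, and the joint tables equalled the single ones, so they gave no other value of Cd93. The filter at an FPKM of 5 removes no named gene of the 12 highest and 12 lowest.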

Other observations

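The tests of counting error, of the loss of IL-17D, of T cells, of macrophages, of endothelial cells, of fibroblasts and of a mix of subsets, the demand for reads in at least 3 islet genes and the values that cross the 2 pairs were chosen after the results had been seen.

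Genes at least 2-fold apart in the CD93 pair were set against the differences of the KO and WT pair. Of the 252 genes at least 2-fold higher in CD93-positive ILC3s, 182 were measured in the KO and WT pair, and 38 of them were at least 2-fold lower in the KO library, against a mean of 20.6 (central 95% 13 to 29) in random lists of the same size and expression. At the same time 21 were at least 2-fold higher, against 24.3 (16 to 33). Among the 38 were the lipid synthesis genes Idi1 and Insig1, the receptor genes Il1r2 and Tnfrsf9, and Foxs1 and Igfbp4. Of the 133 genes lower in CD93-positive ILC3s and measured in both, 22 were lower in the KO library (random mean 13.6, 7 to 20), among them Ifit2, Ifit3, Hspa1a, Hspa1b and Dntt. Another 23 were higher, within the range of the random lists (16.3, 10 to 24), among them Klrb1c, Klrd1, Gzma and Fasl. The medians of both sets in the KO and WT pair, -0.053 and 0.10, lay within the random lists. The sets therefore did not move as a whole. Genes lower in the KO library exceeded the random range in both opposite sets, so the overlap followed no single direction. Random lists were matched on expression and not on reads, with which the share of 2-fold genes varied in the KO and WT pair.

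Pancreatic acinar genes made up most of the highest differences of KO over WT, while the highest gene of the KO library was Actb. A list of 51 such genes was written after 24 of them had been seen among the largest differences, and Reg1 is also on the epithelial list; intestinal epithelium also expresses Reg1, Zg16 and Gp2. In the KO library 135791 recovered reads (0.503% of the scaling total) fell in the list, against 442 (0.00169%) in WT. With Amy2a2 alone of the near-identical copies Amy2a2 to Amy2a5, these were 76718 (0.284%) against 437. Of the 27 listed genes whose values had not been seen, 12 were tabulated for this pair. Counted on FPKM without the added 1, 91.7% of these 12 were at least 2-fold higher in the KO library. Gp2 (FPKM 19.1 and 3.51) and Try5 (15.9 and 3.23) were the most abundant. Serpini2 (0.866 and 0), also counted, lay under the FPKM of 1 of a measured gene. Such a rise is what pancreatic tissue or its RNA in that sample may give, although a sort for CD45 and CD90.2 would remove acinar cells. Uneven amplification of single genes would send genes both ways. By the same count 8.33% of the 12 were lower, between the bounds set beforehand. That share is 1 gene, Cpn1 (0 and 0.883), which lay under the FPKM of 1 of a measured gene. A share that rests on 1 such gene cannot tell uneven amplification apart. Expression by ILC3s without IL-17D cannot be told apart either with 1 library. Acinar transcripts did not need the loss of IL-17D to be present, since the CD93 pair, from WT mice, had them too (values below). Whether the same source raised them in the KO library was not tested. Islet genes had 212 reads in KO against 19 in WT, beyond the bound set beforehand. That bound was wrong because 1 gene could meet it. All 212 reads came from Chgb, and Gcg went the other way. Ttr, without recovered reads, was higher in KO (FPKM 1.09 and 0). In this pair 910 genes are at 0 in 1 library. Of the 51 acinar genes, 37 were tabulated for the CD93-positive and CD93-negative libraries of WT mice. They held 0.0732% and 0.112% of the scaling totals, and Ctrb1 had an FPKM of 185 and 297.

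Many genes lay far apart between the KO and WT libraries, with 910 of 9254 genes at 0 in 1 library although the pair had at least 50 reads; a binomial split of the reads gives 0. Counting error at the sequencing depth therefore cannot account for them. The share of genes at least 2-fold apart among those with at least 10000 reads was 0.108 times that among genes with 100 to 1000 reads. This is what few starting molecules or uneven amplification may give, and the genes at 0 were split evenly between the libraries (452 and 458). A part due to the loss of IL-17D cannot be told apart from a difference between 2 libraries; 0 of 23 ILC3 core genes differed by 2-fold.

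LTi-like and cytokine genes were higher in the CD93-positive library; more T cells, which could bring Cd4, would raise the T cell list, but its median was -0.995. Macrophages, which can carry CD93, would raise their own genes at least as much. The median of their list lay below that of the LTi-like list in 99.4% of 10000 bootstrap draws of the members. Lyz2 had an FPKM of 1.69 and 1.10, C1qa 5.83 and 2.45 and Cst3 86.0 and 82.1. The draws resample genes, not libraries, and members high in both libraries, such as Fcer1g (327 and 255), have little room to move. The macrophage list itself was higher (median 0.32, percentile 99.77), with 1 of 18 genes at least 2-fold higher and 0 lower, and Cd14 had 10.4 and 5.53. Some macrophages in the CD93-positive sort are therefore not excluded. In the list of fibroblasts and smooth muscle 4 of 5 genes were higher (median 1.25), but Col1a1, Col1a2, Col3a1 and Dcn, abundant in fibroblasts, had a summed FPKM of 0.312 and 0.484, in the CD93-positive library 0.0275 times that of Lum, which argues against fibroblasts; other stromal cells were not tested. Endothelial cells, which carry CD93 and which a sort for CD45 would remove, cannot be told apart from the other explanations with 5 measured genes that go both ways (below the LTi-like list in 73.7% of draws): Cldn5 (23.2 and 4.55) and Eng (11.6 and 3.65) were higher and Cdh5 was not (0.569 and 1.67). Another mix of LTi-like and NCR-positive ILC3s in the sorts is a candidate explanation, with the NCR-positive list at -0.76. Bulk libraries cannot tell such a mix from a difference within cells. Other cells in the CD93-negative sort were not tested. The T cell and intestinal epithelial lists were higher in that library (medians -0.995 and -0.61 for CD93-positive minus CD93-negative). Dntt had 1 read in CD93-positive and 555 in CD93-negative ILC3s.

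Some lists with fewer than 5 measured members are given as values. In the CD93 pair the Y-linked genes Ddx3y (FPKM 42.1 and 47.8) and Eif2s3y (30.1 and 29.4) were expressed, with Kdm5d and Uty. In the KO and WT pair Xist had 11.3 and 6.57. No other gene of the sex-linked list was measured in either pair, so the mice of the 2 pairs may differ in sex. The mast cell gene Cpa3 had 0 in KO and 4.62 in WT, and 0.0563 and 1.23 in CD93-positive and CD93-negative ILC3s; Hdc of the first pair (1.48 and 1.09) and Il3ra of the second (17.3 and 16.5) were less than 2-fold apart. Of 4 red blood cell genes, 2 were lower in the KO library, Hbb-bs (0 and 1.80) and Hbb-bt (0 and 1.47), while Hba-a1 had 11.7 and 10.1 and Hba-a2 13.1 and 9.08; in the CD93 pair 0 of 4 differed by 2-fold. Il1b, the only measured gene of the neutrophil list in the KO and WT pair, was higher in KO (2.95 and 0.784), and in the CD93 pair 0 of 3 differed by 2-fold. Ret, the only measured gene of the list of enteric glia and neurons in the CD93 pair, was higher in CD93-positive ILC3s (18.7 and 5.38). Of 4 B and plasma cell genes of the CD93 pair, 0 differed by 2-fold. Clone names took 34.4% of the summed FPKM in the KO and 36.8% in the WT library, where Gapdh had an FPKM of only 6.11 and 2.83 and Actb 21853 and 31207.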
